A study of Mus musculus with 2 samples.

How the data were processed

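RNA from intestinal epithelial cells of wild-type male mice was measured on 2 one-colour Agilent arrays, 1 after incubation of intestinal segments with vehicle and 1 after incubation with cholic acid, per the labels. Per the labels' protocols, RNA was isolated with a phenol reagent and a column kit, amplified as cRNA and labelled with Cy3. The deposited scanner files hold spot intensities from Agilent Feature Extraction for array design 028005, with probe positions on mm9, per the file headers. The file headers give Feature Extraction version 10.7.1.1, whereas the submitters' processing notes list 9.5.1.1. The processed signal in these files is an intensity that was background-subtracted and detrended within the array, with a surrogate value for dim spots, per the file headers. The same deposited files hold other columns with flags for each spot, among them well above background, positive and significant, saturated, non-uniform and population outlier. The authors also deposited a table of processed intensities for 55681 probes, with a median of 10.09 on each array. Its sorted columns lay within 0.024% of each other, so it holds quantile-normalized values on a linear scale, and their log2 values correlated across probes with the scanner signal at Pearson r = 0.99987 for vehicle and 0.99984 for cholic acid.

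Each array carried 62976 spots, of which 3671 were controls. Spots with a non-uniformity or population outlier flag were left out, 124 on the vehicle array and 119 on the cholic acid array. No spot was saturated on either array. Log2 processed signals were averaged over the spots of a probe, giving 55681 non-control probes. Of these, 24202 were well above background on the vehicle array, 24449 on the cholic acid array and 22614 (40.61%) on both. Because under 50% of the probes were well above background on both arrays, the 75th percentile over the probes well above background on both was subtracted from each array. That percentile was a signal of 1060 on the vehicle array and 741 on the cholic acid array. Gene names came from the accessions in the files, matched without versions to a RefSeq gene table of assembly GRCm38.p6 that was used for names alone. By this route 27235 probes were named by accession, 3581 by current symbol and 560 by synonym, 1422 kept the name in the files, and 22883 had no gene name.

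A gene's value was the mean over its probes well above background on both arrays, and its difference was cholic acid minus vehicle on the log2 scale. In all 12812 genes were measured on both arrays, 9679 with 1 probe and 3133 with several. Genes whose probes were well above background on 1 array alone were given a bound: the brighter log2 signal against the higher of the dim probe's own signal and the lowest signal among probes well above background on the dim array. With 1 array per group there is no residual spread between replicates, so no p-value, standard error or test of the conditions was computed, and genes were counted by size, at least 2-fold apart. The number of arrays limits the precision. As a yardstick of single genes, the robust SD of the log2 differences of the 1000 genes nearest in mean signal was taken.

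Before the data were examined, 40 gene lists, the rule for named genes and most of the alternative settings were fixed. Each list's median was placed among the medians of 10000 random lists of the same size, drawn from 20 bins of mean signal. This describes these 2 arrays and tests nothing about the conditions. A list was said to stand apart outside the central 95% of the random lists, and lists with fewer than 3 measured members got no median. Named genes were, first, the 12 with the largest difference in each direction among genes at least 2-fold apart, in the brighter part of the measured genes by median, with all probes going the same way and without predicted or clone names. Next came 10 genes taken whatever their values, among them Slc15a1, Ppara, Nr1h4, Pdk4, Angptl4, Cpt1a, Fabp1, Cyp4a10 and Fgf15. Some genes that the rule names are not reported here. The next part was the members of each list at least 2-fold apart, or otherwise up to 4 members with the largest difference. The last part was the 4 largest bounds in each direction, again without predicted or clone names. Other list members are cited as examples and were chosen after their values were seen. A further 4 lists were written after the first results were seen and before their own values were.

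The alternatives were the 75th percentile over all non-control probes, centring on the median, quantile normalization, a loess of the difference on mean signal, normexp background correction with an offset of 50, the authors' processed values, 3 other filters on dim probes, the brightest probe per gene, agreement of all probes of a gene, 1.5-fold and 3-fold limits, and the positive and significant flag for bounds. A lowess on probe GC content with a span of 0.3, scaling on the spike-ins, and the GC lowess or the loess followed by the 75th percentile scaling were added after seeing the data. So were ranges of the ratio of higher to lower genes from 1000 redraws of the genes, and 10000 relabellings of PPARα targets and other absorptive genes within 5 bins of signal. The calculations used R 4.3.3 with limma 3.58.1 for normexp, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.

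The counting of genes and the placing of lists were tested on simulated data. With 200 of 12812 genes changed and the spread between replicate spots as noise, counting at 2-fold recovered 0% of genes changed 1.5-fold, 51.5% of those changed 2-fold and 100% of those changed 3-fold or 4-fold, and called 0 unchanged genes. These rates follow from that noise, whose SD of 0.11 is small against the 2-fold limit. The real differences of all genes had a robust SD of 0.48, so the rates say nothing about false calls from differences between animals or segments. Of 300 unshifted lists of 15 genes, 3.33% lay outside the central 95% of random lists, and 89.67% of lists shifted by 0.5 on the log2 scale lay above it. The unshifted lists were drawn gene by gene from the same differences, so this check does not cover lists of co-regulated genes.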

Results

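Gene expression was profiled in epithelial cells of mouse intestinal segments kept for 2 h with cholic acid, a primary bile acid, at 0.5 µM, or with a vehicle of 0.05% DMSO and 0.25% ethanol. The labels give the solvent for the vehicle alone, so whether it was the same with cholic acid is not known. The titles read as small intestine (S_I) segments, but the labels do not say where along it they were taken, or from how many mice. The series asks which genes are candidates for bile acid-dependent regulation through PPARα, a nuclear receptor that induces fatty acid oxidation genes. There was 1 array per condition, on the same slide and in the same scan, so no difference below has a replicate check. The arrays correlated across genes at Pearson r = 0.9775, where genes are not independent replicates. Among 226 probes spotted 10 times and measured on both arrays, the SD of a log2 difference between single spots had a median of 0.11, and of 0.18 among the dimmer of them. These values describe the measurement on an array, not the spread between animals or segments.

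PPARα targets of lipid handling and other absorptive genes were, as groups, lower on the cholic acid array. Slc15a1, the proton-coupled peptide transporter PepT1, was 3.35-fold lower (log2 difference -1.75), against a spread of 0.38 among the 1000 genes nearest in signal. Slc25a20, the mitochondrial carnitine-acylcarnitine carrier, was 2.67-fold lower. The fatty acid transporter Cd36 was 2.28-fold lower, and the apolipoproteins Apoa4 and Apoa2 were 3.45-fold and 3.33-fold lower. Fads1, a fatty acid desaturase, was 3.30-fold higher, from dim signals of 17.8 (vehicle) and 41.1 (cholic acid). The spread of its nearest genes was 0.55.

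In the list of PPARα targets of fatty acid oxidation, 32 of 35 members were measured on both arrays, of which 0 were at least 2-fold higher and 2, Slc25a20 among them, at least 2-fold lower. Acadm, medium-chain acyl-CoA dehydrogenase, was 1.92-fold lower and the acyl-CoA thioesterase Acot3 1.91-fold higher. The list median was -0.19, at percentile 3.11 of random lists, within their central 95%. In the list of PPARα targets of lipid uptake, binding and storage, 27 members were measured, with 1 (Fads1) at least 2-fold higher and 4 (Apoa4, Apoa2, Cd36 and the acyl-CoA synthetase Slc27a2) at least 2-fold lower. Its median was -0.30, at percentile 0.02, below the random lists. That median leaves out the member Scd1, which was well above background on the cholic acid array alone and at least 2.655-fold higher there. Among targets chosen in advance, Cyp4a10 (-0.81), Angptl4 (-0.65), Pdk4 (-0.49), Fabp1 (-0.27) and Cpt1a (0.14) differed by less than 2-fold, although the brighter of the 2 probes averaged for Cyp4a10 was at -1.22 and the dimmer at -0.40. Ppara itself differed by -0.22 with its 3 probes not going the same way, and the 2 probes of Cpt1a also went opposite ways.

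Nutrient carriers had a median of -0.42 over 31 measured genes, at percentile 0.00 of random lists, with 6 at least 2-fold lower and 1 higher. The 6 were Slc46a1, the proton-coupled folate transporter (5.79-fold), Slc22a4 (4.04-fold) and Slc22a5 (2.53-fold), organic cation and carnitine transporters, the thiamine transporter Slc19a3 (4.01-fold), the glucose transporter Slc2a2 (2.00-fold) and Slc15a1. The monocarboxylate transporter Slc16a1 was 2.00-fold higher, from dim signals of 22.6 (vehicle) and 31.6 (cholic acid). Brush border hydrolases had a median of -0.40 over 18 genes, at percentile 0.09, with 16 below 0 and 0 at least 2-fold apart: the neutral endopeptidase Mme (-0.95), Ace (-0.71) and sucrase-isomaltase Sis (-0.68) were examples. Genes of chylomicron assembly had a median of -0.56 over 16 genes, at percentile 0.01, with 15 below 0. Among them were Apoc2 (-0.94), Apoc3 (-0.79) and the acyltransferase Dgat2 (-0.69). General enterocyte markers also lay below random lists (median -0.33 over 12 genes, percentile 1.08), while T cell markers lay above them, as described further on. Many enterocyte markers are members of the other absorptive lists. Alpi, Sis, Lct and Anpep also count as hydrolases. Apoa1, Apoa4, Fabp1 and Fabp2 each count as enterocyte markers, in chylomicron assembly and in PPARα lipid handling. Apoa4, Fabp1 and Lct also count as proximal gut markers, described further on. These medians are therefore not independent of each other, and the enterocyte median largely repeats the other lists.

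A bile acid gene gave the largest difference among genes measured on both arrays. Fabp6, the ileal bile acid-binding protein, was 39.9-fold higher on the cholic acid array (log2 difference 5.32, spread of nearest genes 0.41). Slc10a2, the apical sodium-dependent bile acid transporter, was 4.79-fold higher, with its 2 probes going the same way. The efflux transporter Abcc4 was 2.37-fold higher, while Slco2b1 (2.17-fold) and the sterol hydroxylase Cyp27a1 (2.01-fold) were lower. Abcc4 was dim, with signals of 19.7 (vehicle) and 32.6 (cholic acid), and so was Cyp27a1, with 45.78 and 15.94. Targets of the bile acid receptor FXR had a median of 0.44 over 9 measured genes, at percentile 99.55, with Fabp6 and Nos2 (3.19-fold) at least 2-fold higher and Cyp3a11 (2.80-fold) lower. The median of the list of bile acid carriers, receptors and enzymes was 0.26 over 13 genes, at percentile 90.44, within the random lists. The receptor gene Nr1h4 differed by -0.11, and Fgf15, an FXR target hormone of the ileum, was not well above background on either array.

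**Figure D1:**
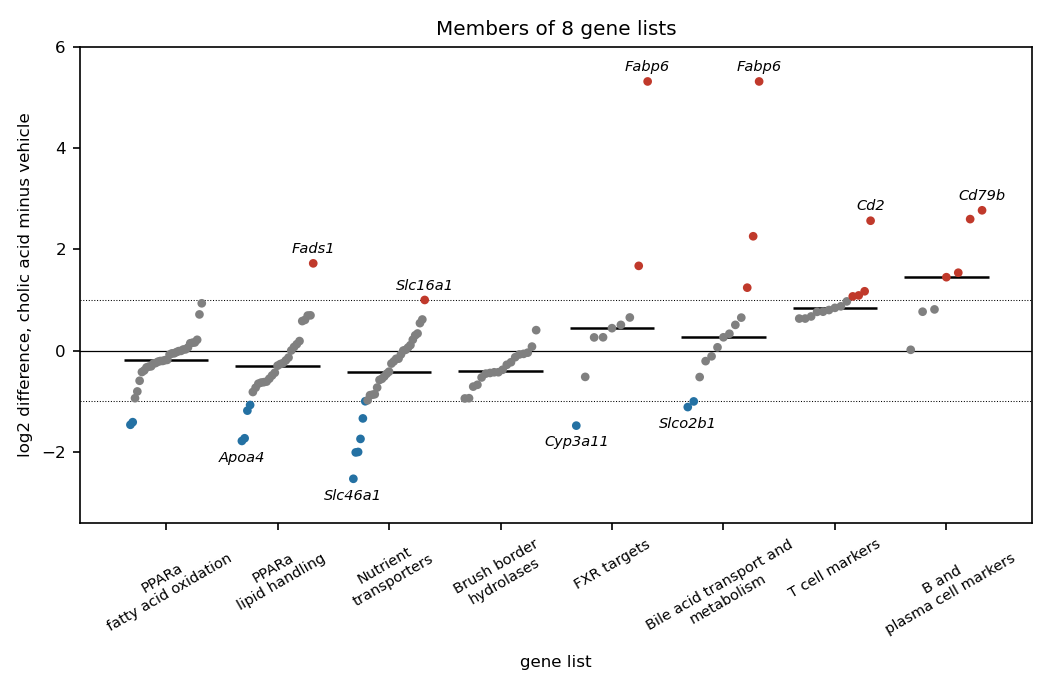
Log2 differences (cholic acid minus vehicle, vertical axis) of the members of 8 gene lists, 1 point per gene measured on both arrays, with black bars at list medians, dotted lines at 2-fold, and red and blue points at least 2-fold higher and lower. Fabp6 stands at 5.32 and Slc46a1 at -2.53, and medians run from -0.42 for nutrient transporters to 1.45 for B and plasma cell markers, with 1 array per condition.

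Over all 12812 genes measured on both arrays, 835 (6.52%) were at least 2-fold higher in cholic acid and 263 (2.05%) at least 2-fold lower. The split depended on the scaling: higher genes made up 76.05% of these calls in the main setting, but 43.97% with the percentile taken over all non-control probes, 58.16% with centring on the median, 57.04% with loess, 51.39% with quantile normalization and 51.44% in the authors' processed values. With the scalings added after seeing the data, the share was 59.83% after correction for probe GC content and 2.45% with scaling on the spike-ins. The median difference of all genes was 0.08 in the main setting and was shifted from it by -0.23, -0.13, -0.12, -0.15, -0.15, -0.13 and -0.89 in that order, and by 0.10 with normexp. When the 75th percentile scaling was kept, the share of higher genes was 76.09% after the GC correction and 54.34% after loess. Relative to the median of all genes in the same setting, the lipid handling, nutrient carrier, hydrolase and chylomicron lists were lower and the FXR list higher in each of the 9 alternatives that can move such a relative value, while the bile acid list was higher in 6 of 9. The other 3 shift every gene alike. The FXR list's margin ran down to 0.032.

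Among bright genes with all probes going the same way, the largest positive differences after Fabp6 were those of the splicing factor Cwc22 (9.99-fold), Duoxa2, the maturation factor of a dual oxidase (9.78-fold), the brush border phospholipase Plb1 (9.06-fold) and the B cell receptor component Cd79b (6.83-fold). S100g, the calcium-binding protein calbindin-D9k, was 6.12-fold higher, the chemokine Cxcl10 5.92-fold, the actin-severing protein Gsn 5.60-fold, Ly6d 5.54-fold and the T cell adaptor Lat (log2 difference 2.38). Cmya5 (4.75-fold) and Syn3 (4.72-fold) completed the 12. On the other side were the eotaxin Ccl24 (6.48-fold lower), the ubiquitin ligase Mid1 (6.22-fold), the kinase Sgk1 (6.16-fold), Slc46a1, Reg1 (5.44-fold), the transcription factor Onecut2 (4.92-fold), Nxph3 (4.47-fold), Slc22a4, the ectonucleotidase Enpp3 (3.74-fold), Apoa4, Slc15a1 and Apoa2. Each of these kept its sign in every alternative setting that measured it. Of the genes with several probes, 127 of 128 higher and 45 of 46 lower genes had all probes going the same way, and 54 and 22 had each probe at least 2-fold apart. The agreement in direction is partly built in, because these genes were called on the mean of the same probes. In mm9 coordinates, per the file headers, the probe of Fabp6 lies on chromosome 11 from 43410973 to 43411032, and that of Slc15a1 on chromosome 14 from 121859041 to 121859100. Exon and UTR annotation of mm9 was not used here.

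**Figure D2:**
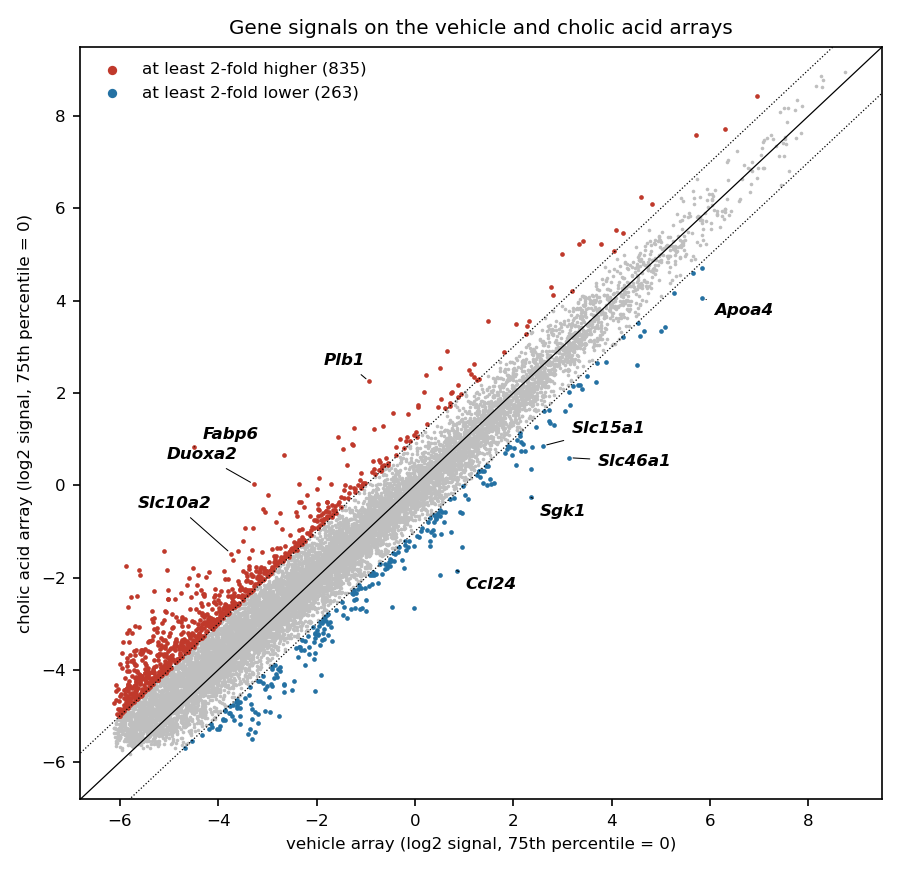
Log2 signal of each gene on the vehicle array (horizontal axis) and the cholic acid array (vertical axis), each with its 75th percentile set to 0, with dotted lines at 2-fold, red points for the 835 genes at least 2-fold higher in cholic acid and blue points for the 263 lower. Red points crowd at the dim end, and among the brighter 6406 genes the counts were 189 and 148.

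A further 504 genes were well above background on the cholic acid array alone and 432 on the vehicle array alone, so they have only a bound. The bound was at least 2-fold for 261 and 62 of them. Aass, the first enzyme of lysine breakdown, was at least 154-fold higher in cholic acid, the mannose-binding lectin Mbl2 at least 97.8-fold, the goblet cell protein Retnlb at least 97.7-fold and the phospholipase Pla2g4c at least 34.0-fold. Pla2g2a, a secreted phospholipase, was at least 18.6-fold lower, and Rbm46os, Slc6a3 and Vmn1r101 were at least 6.40-fold, 6.07-fold and 5.23-fold lower.

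Markers of lymphocytes were higher on the cholic acid array. All 13 T cell markers had positive differences (median 0.84, percentile 100 of random lists), with Cd2 5.92-fold, Gzmb 2.25-fold, Cd3d 2.13-fold and Cd8b1 2.10-fold higher. Cd2 rests on 1 probe, dim on the vehicle array at 32.6 and at 135 in cholic acid, and its other probe was not well above background on either array. The B and plasma cell list had a median of 1.45 over 7 measured genes, at percentile 100, led by Cd79b, Pou2af1 (6.06-fold), Cd79a (2.91-fold) and Mzb1 (2.73-fold). Smooth muscle markers also stood above random lists (median 0.83 over 6 genes, percentile 99.18), as did enteroendocrine markers (median 0.37 over 13 genes, percentile 99.06), where the glucagon gene Gcg was 2.02-fold higher. The smooth muscle list was dim, with a median vehicle log2 signal of -4.07 and with Cnn1 at signals of 15.8 (vehicle) and 36.9 (cholic acid). Relative to all genes the enteroendocrine list was higher in 8 of those 9 alternatives. Distal gut markers had a median of 0.88 over 6 genes, at percentile 99.94, with Fabp6, Slc10a2 and Gcg at least 2-fold higher and Cubn 1.92-fold lower. That median lies between Gcg and Pyy (log2 difference 0.74), which also count as enteroendocrine markers. Fabp6 and Slc10a2 also count in the bile acid list, so the distal list is not separate from these lists. Proximal gut markers had a median of -0.19, within random lists, with Onecut2 and Apoa4 lower and S100g higher. The list medians of goblet (0.05), Paneth (-0.09), tuft (0.43), stem (0.19), myeloid (0.17), fibroblast (0.52), endothelial (0.40) and pancreatic acinar cells (-0.07) lay within random lists. Among their members, Thy1 (4.11-fold), which mouse T cells also express, and Dcn (3.03-fold) were higher in the fibroblast list. Gfi1b was 2.89-fold and Dclk1 2.77-fold higher (tuft cells), from dim vehicle signals of 28.3 and 18.2. Itgax was 2.09-fold higher (myeloid cells), while Clps was 2.13-fold lower (pancreatic acinar cells). Fewer than 3 members were measured for nerve and glia, adipocyte and red blood cell markers, although Hbb-b2 (2.87-fold) and Hba-a1 (2.30-fold) were higher. Their vehicle signals were 20.7 and 74.6.

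Several signalling and stress lists also stood apart from random lists. Interferon-stimulated genes had the lowest median of any list, -0.68 over 18 genes (percentile 0.00). Ifi44 (5.45-fold), Rsad2 (2.97-fold), Ifit3 (2.55-fold) and Oas1a (2.51-fold) were lower, but Cxcl10 and Gbp2 (2.04-fold) were higher. Inflammatory genes had a median of 0.46 over 15 genes (percentile 99.85), with Cxcl10, Nos2, Ccl4 (2.71-fold) and Ccl3 (2.44-fold) higher and 0 at least 2-fold lower. Glucocorticoid receptor targets had a median of -0.51 over 10 genes (percentile 0.09), with Sgk1, Mt2 (2.27-fold) and Tsc22d3 (2.27-fold) lower and Fkbp5 (2.09-fold) higher. Clock genes had a median of -0.44 over 15 genes (percentile 0.00), including Nr1d1 (2.17-fold lower). Rora was 2.00-fold higher, from dim signals of 20.3 (vehicle) and 28.4 (cholic acid). Immediate early genes had a median of -0.29 over 27 genes (percentile 0.03), with Egr1 (2.52-fold), Fos (2.33-fold), Zfp36 (2.29-fold) and Gadd45a (2.00-fold) lower and Dusp2 (2.95-fold) and Nr4a2 (2.11-fold) higher. LXR targets and lipogenic genes had a median of -0.33 over 14 genes (percentile 0.45), where the desaturase Scd2 (4.57-fold), the lipogenic regulator Srebf1 (3.16-fold) and the sterol exporter Abcg8 (2.05-fold) were lower. Scd1, a member with only a bound, was higher, as given above. Proliferation genes had a median of 0.56 over 18 genes (percentile 99.86), with the replication factors Mcm5 (2.39-fold), Mcm3 (2.12-fold) and Mcm6 (2.10-fold) and the kinase Cdk1 (2.35-fold) higher. The 2 probes averaged for Cdk1 were dim on the vehicle array, at 18.8 and 22.6. Hypoxia genes had a median of -0.26 over 14 genes (percentile 2.25), with Ankrd37 3.31-fold lower and Hk2 2.12-fold higher.

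The list of targets of the drug receptors PXR and CAR had a median of -0.23 over 24 genes (percentile 3.09, within random lists), with Cyp3a11, Cyp2b10 (2.51-fold), Cyp2c29 (2.31-fold), Cyp2c65 (2.17-fold) and Cyp2c66 (2.14-fold) lower and Aldh1a7 4.02-fold higher. Medians within random lists were also found for vitamin D and AHR targets (0.13), sterol synthesis (-0.05), heat shock (0.10), the ER stress response (0.03), oxidative stress with metallothioneins (-0.08) and reference genes (-0.04). In the ER stress list Chac1 (3.17-fold) and Herpud1 (2.20-fold) were lower and Psat1 (2.21-fold) higher, and in the metallothionein list Mt1 was 2.84-fold lower with its 2 probes differing in size. The tubulin gene Tubb5, a reference gene, was 2.01-fold higher, and Actb differed by 0.35.

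**Figure D3:**
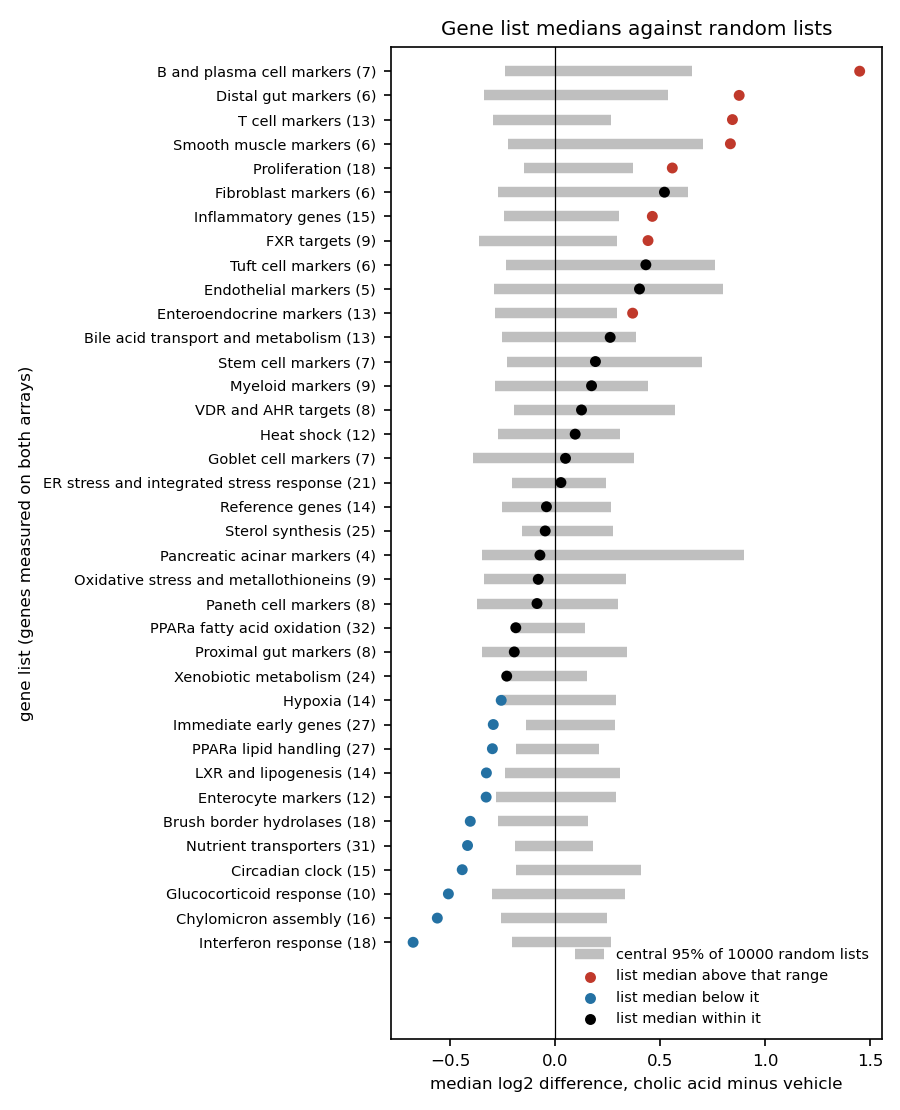
Median log2 difference (cholic acid minus vehicle, horizontal axis) of each gene list fixed in advance with at least 3 measured members (number in parentheses), with grey bars for the central 95% of 10000 random lists matched on signal and red, blue and black points above, below and within it. The 4 lists written later are not drawn. B and plasma cell markers stand highest at 1.45 and interferon genes lowest at -0.68; with scaling on the spike-ins, all genes shift by -0.89 and 7 of the lists above the random range change sign.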

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

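The tests on probe GC content, on the signal-dependent trend, on dim probes, on gut position and on the lymphocyte list were set before their results were seen; the FXR tests, the comparison of cell type lists, and the ratios with the scaling kept or the median put back, were set afterwards. Probes without a gene name, which enter no comparison above, carried signal above the negative controls: 5961 of 22883 (26.05%) were well above background on both arrays, against 1 of 308 negative control spots on each. Of these unnamed probes, 539 were at least 2-fold higher in cholic acid and 90 lower. Probes of lincRNA regions, which include many of them, had 269 higher and 59 lower among 3460 well above background on both arrays. Control spots with ERCC sequences were well above background at 154 of 2772 spots (5.56%) on the cholic acid array and 125 of 2772 (4.51%) on the vehicle array, against 0.325% of negative control spots. By probe the order was reversed, with any such spot at 19 of 96 ERCC probes on the cholic acid array and 30 of 96 on the vehicle array.

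More genes were at least 2-fold higher than lower in cholic acid, by a ratio of 3.175. After the GC correction it was 1.489, which met the limit set in advance for GC content as the cause, but that correction also shifts all genes by -0.13, and in a test chosen after this was seen, with the 75th percentile scaling kept, the ratio was 3.182 (2.79 to 3.695 when genes were drawn again 1000 times), which argues against GC content as the whole cause. Dim probes near background and a signal-dependent trend may contribute, since the ratio was 1.277 (1.034 to 1.612) among the brighter 6406 genes and 1.328 after a loess on signal, both meeting their limits set in advance. With that loess and the scaling kept, as in the later GC test, it was 1.19 (1.051 to 1.366). Centring on the median alone gave 1.39, so these causes cannot be told apart from the centring. With the median of all genes put back, the ratios were 2.785 in the brighter genes and 2.628 with loess. That step adds the same constant to every gene and raises the ratio by construction, so these values do not speak against either cause. No biological explanation of this ratio was tested.

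As a list, distal gut markers, Fabp6 and Slc10a2 among them, were higher in cholic acid, although Cubn was lower. Activation of FXR by the bile acid would raise Fabp6 and lower Slc10a2; Slc10a2 was higher by 2.26, which met the limit first stated against FXR, but that limit was set aside after the value was seen, since a single gene of the group does not exclude FXR. For Fabp6 FXR stays a candidate explanation that these values do not decide. The other 8 measured FXR targets had a median of 0.35, above the random range of -0.38 to 0.28. This test was chosen after the whole FXR list was known to stand at 0.44, so it largely restates that median. Nos2, one of the other targets, also counts in the inflammatory list, and Fgf15 was not well above background on either array. A segment taken from further down the gut was tested with a further pair of lists, in which the distal median (-0.61) minus the proximal median (-0.48) was -0.13, inside the range of -0.49 to 0.45 of random pairs. The titles read as small intestine (S_I) without the place along it, and with 1 array per condition position and treatment cannot be told apart; both further lists lay below random lists.

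Lymphocyte genes were higher in cholic acid in the T cell and B cell lists. A lower share of enterocytes would raise the markers of other cell types alike. The medians of 5 such lists (T cell, B cell, goblet, Paneth and stem) spanned 1.54, beyond the 0.20 to 1.00 of random lists. That span runs from Paneth (-0.09) to B cell markers (1.45), which are part of the pattern itself, and the comparison was set after seeing the data. It speaks at most against a lower enterocyte share as the whole cause. A contribution stays open, since enterocyte markers were lower (median -0.33). A further list of 28 measured lymphocyte genes had a median of 1.04, above the random range of -0.13 to 0.29, with 17 at least 2-fold higher and 0 lower, which is consistent with more lymphoid cells in the cholic acid segment. Of the 28 genes in that list, 26 lay above 0 and 2 below. The list's most abundant members did not move together: the 2 lower were Cd74 (-0.24) and H2-Ab1 (-0.47), which other antigen-presenting cells and enterocytes also express. A response of resident lymphocytes to cholic acid stays open, and was not tested.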

How the results depend on the processing

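No paired analysis was possible because each condition has 1 array, and for the same reason no array could be left out. Higher and lower genes numbered 423 and 539 with the percentile over all non-control probes, 444 and 420 with quantile normalization, 448 and 423 in the authors' processed values, 270 and 104 with normexp, 2904 and 619 with no filter on dim probes, 1489 and 526 with probes well above background on at least 1 array, and 189 and 148 in the brighter genes, where fewer genes are counted. Higher genes numbered 545 with centring on the median and 498 with loess; a loess with the percentile scaling kept, added after seeing the data, gave 470 and 395. A 1.5-fold limit gave 2271 and 985, and a 3-fold limit 177 and 42. Scaling on the spike-ins, chosen after seeing the data, gave 108 and 4300: the 7 spike-in probes differed by 0.89 (SD 0.05 between probes) after the main scaling. Of the 835 and 263 genes of the main setting, 423 and 263 were shared with the percentile over all probes, and 446 and 260 with the authors' values. Genes with a bound numbered 936, and 2378 with the positive and significant flag. Except where the construction shows it, the cause was not tested.

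With the percentile over all probes the medians were -0.42 for PPARα oxidation, -0.53 for lipid handling, -0.65 for nutrient carriers, -0.63 for hydrolases, 0.21 for FXR targets and 0.034 for bile acid genes. With centring on the median the first 4 were -0.32, -0.43, -0.55 and -0.54. Lipid handling was -0.51 with quantile normalization, -0.48 with loess and -0.50 in the authors' values; bile acid genes were -0.081 with quantile normalization and -0.077 in the authors' values, turning their sign. PPARα oxidation was -0.077 with normexp. After the GC correction, chosen after seeing the data, PPARα oxidation was -0.29, nutrient carriers -0.51 and FXR targets 0.25. Spike-in scaling gave -1.08, -1.19, -1.31, -1.30, -0.45 and -0.63 for the 6 lists. It also turned the medians of inflammatory genes (-0.43), proliferation (-0.33), enteroendocrine (-0.52), T cell (-0.049), smooth muscle (-0.058) and distal gut markers (-0.016). None of the alternatives fixed in advance turned the sign of a list that stood apart, nor of a named gene at least 2-fold apart. Of 170 named genes, 140 moved by less than the spread of their nearest genes with normexp, and 160 or more with each other such alternative that measured all 170. Leaving out saturated probes moved nothing, since 0 spots were saturated.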

Other observations

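The test on strain-variable genes was set before its values were seen, and the comparison of PPARα targets with other absorptive genes afterwards; the 3 genes that follow were chosen after their values were seen. Some genes were well above background on the cholic acid array alone by wide bounds. H2-Ea, a class II antigen-presentation gene that some mouse strains lack, was at least 31.2-fold higher, and the lymphocyte genes Ms4a1 (at least 16.1-fold) and Ccr7 (at least 11.1-fold) stood with it.

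A hypothesis is that the mice behind the arrays differed in genetic background, since H2-Ea was well above background on the cholic acid array alone. Pla2g2a, another gene with null alleles in some strains, was well above background on the vehicle array alone. A list of other genes known to vary between strains had 18 members measured on both arrays, with a median absolute log2 difference of 0.45, at percentile 93.72 of random lists and inside their range of 0.16 to 0.50. Of these 18 genes 1 was at least 2-fold apart (5.56%), against 8.57% of all genes. The list, which holds Itln1 through a synonym, does not settle the question, so strain and treatment cannot be told apart for these genes. Lymphocyte markers were also higher on the array where H2-Ea was seen, and whether more lymphoid cells account for H2-Ea was not tested.

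Another hypothesis was that PPARα targets differ from the general lowering of absorptive genes. The 59 pooled PPARα targets had a median of -0.21 and the 61 other absorptive genes (carriers, hydrolases and chylomicron genes) -0.43. The difference of 0.22 lay just outside the range of -0.21 to 0.21 given by 10000 relabellings of the genes, but inside the range of -0.18 to 0.22 when relabelled within 5 bins of signal. The call changes with the setting: the difference lay above the signal-matched range with quantile normalization (0.28), loess (0.29), normexp (0.26), the authors' values (0.30) and in the brighter genes (0.22), and within it with the brightest probe per gene (0.22) and after the GC correction (0.17). The other alternatives left it unchanged and within. Whether PPARα targets were lowered less than other absorptive genes stays open, and a stronger lowering was not seen in the pooled lists. The genes are not replicates, and this describes these 2 arrays.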
